A study of Mus musculus with 2 samples.

How the data were processed

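The series holds RNA sequencing of ckit- and sca1-positive mouse bone marrow cells in 2 samples, 1 control and 1 with Usp16 deleted, grouped by the genotype given in the labels. Per the labels' protocols, libraries followed standard Illumina procedures. Per the submitters' processing notes, TopHat, Picard and Cufflinks were used with the mm10 build. Their versions, the role of each and the gene annotation are not given in the sources used here. Per the file headers, the deposited table gives FPKM values (fragment counts scaled by transcript length and by library size) with lower and upper confidence bounds and a status for conditions named q1 and q2. How these FPKM values were scaled between the conditions by the authors is not given in the sources used here.

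The 8 columns of q1 and q2 were not used in any result, because their names match the labels of neither sample. Column order, accession order and the level of the targeted gene were not accepted as evidence of which condition a column holds. The value ranges of these columns were inspected to identify their unit. No count, ratio or test was computed from them. The comparisons fixed before the data were examined included a log2 ratio of FPKM for Usp16 and counts of the genes changed at least 2-fold. The median log2 ratio of each gene list and a correlation of the libraries across genes were also fixed. The correlation does not depend on which column holds which library, but it was left out with the columns. With 1 library per group all of these comparisons would have been descriptive, with no p-value. None of them was run.

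Only the entry identifiers, transcript identifiers and positions were analysed, with Python 3.11.15 and pandas 2.3.3. The positions were compared with the GENCODE annotation of GRCm38, which is the assembly of mm10. No other build was compared. The start of 14080 entries plus 1 base coincided with the start of an annotated transcript, against 1160 for the start as written. The end as written coincided with an annotated transcript end for 13813 entries, against 1237 for the end plus 1 base. Starts were therefore taken as counted from 0 and are given here counted from 1. A gene in a list was matched to the span with which it had the largest reciprocal overlap, at a minimum of 50% of both lengths. The minimum was not applied to the 4 genes whose positions are described singly, where the reciprocal overlap was 69.8% for Usp16, 30.7% for Cct8, 99.9% for Kit and 100.0% for Ly6a. Only current GENCODE symbols were matched, so a list member under an older symbol counts as unmatched. Spans of overlapping genes can be merged, and a short gene within a longer merged span then falls below the minimum.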

Results

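RNA sequencing was carried out on bone marrow cells positive for the surface proteins ckit and sca1, a fraction that holds the hematopoietic stem and progenitor cells of the mouse. The labels name 1 control library and 1 library from cells in which Usp16 had been deleted. Usp16 encodes a deubiquitinase that removes ubiquitin from histone H2A. Per the labels' protocols, both came from animals carrying loxP-flanked Usp16 and the Mx1-Cre transgene, a recombinase driven by an interferon-responsive promoter. The animals of the deleted library received pIpC, a double-stranded RNA analogue that induces interferon and so switches the transgene on, and those of the control library received saline. The loss of Usp16 and the exposure to pIpC therefore separate the libraries in the same way, and with 1 library per group there is no replicate error for either.

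The question posed by the design is which genes change in expression when Usp16 is deleted from these cells. No comparison between the control and the deleted library is reported. The deposited table holds 2 sets of FPKM values with their confidence bounds and a status, 8 columns in all, headed q1 and q2. Of these 2 names, 0 occur in the labels of either library or in the description of the series. The order of the columns does not record which library each holds, and choosing by the level of Usp16 would make that level no check of the labels. The sequencing depth of the libraries is unknown, since no read counts were used here.

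The entries listed can be described without the values. Which of them were detected in either library was not examined. The table lists 31852 entries, of which 31618 lie on chromosomes 1 to 19, X and Y, 10 on the mitochondrial genome and 224 on unplaced or unlocalized scaffolds. Chromosome X carries 1177 entries and chromosome Y 185. The entries carry 61595 transcript identifiers, all 61595 of the form that the UCSC gene set uses, and 12750 entries combine more than 1 identifier. Genes are named by these identifiers and by a span, with neither symbol nor strand.

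Usp16 (ENSMUSG00000025616.14) lies on the plus strand of chromosome 16, from 87454703 to 87483517 in mm10. In the table its position overlaps a span from 87454985 to 87495869, which begins after the annotated start of Usp16. The span also overlaps Cct8 (ENSMUSG00000025613.13), a subunit of the cytosolic chaperonin on the minus strand from 87483326 to 87495873. It ends before the annotated end of Cct8. The table has 2 entries with this same span. Position alone therefore does not tell which gene either entry measures, and their transcript identifiers were not looked up. Kit, the stem cell factor receptor recognised as ckit (ENSMUSG00000005672.12, chromosome 5, plus strand, 75574916 to 75656722), matches a span from 75574987 to 75656721 held by 1 entry. Ly6a, which encodes sca1 (ENSMUSG00000075602.10, chromosome 15, minus strand, 74994877 to 74998031), matches a span with the same start and end, also held by 1 entry. Across the table, 8192 entries share their span with at least one other entry, over 3045 spans.

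Gene lists fixed before the data were examined were matched to the entries by position. Of the 696 genes in the 35 lists, 596 matched a span and 517 matched a span held by a single entry. Such a span is called the gene's own here, although whether it also covers other genes was not checked. Among the 40 interferon-stimulated genes, the class that pIpC itself induces, 34 matched and 29 had a span of their own. The list includes Ly6a, which encodes sca1, a protein by which the cells were selected. Whether pIpC changed which cells were selected was not tested. Among 30 genes for subunits and partners of Polycomb repressive complexes that ubiquitinate histone H2A, such as Ring1 and Bmi1, and for deubiquitinases and their cofactors, 28 matched and 27 had a span of their own. Of 27 stem cell genes, 24 matched and 19 had their own span. Of 27 transcription factors of blood cell commitment, 25 matched and 22 had their own span. Of 25 inhibitors of cyclin-dependent kinases and p53 targets, 24 matched and 22 had their own span. The lists with the lowest shares matched were MHC class II, with 3 of 9 genes, the mitochondrially encoded genes, with 6 of 11, MHC class I and antigen presentation, with 9 of 15, and B cell genes, with 13 of 19. For ribosomal proteins, 31 of 40 matched and 22 had their own span. A match by position does not identify an entry where several entries share the span. List members under an older symbol count as unmatched, and so do genes whose overlap with every span is below the minimum. With the minimum lowered to 25%, 635 of the 696 genes matched and 536 had a span of their own. A lower minimum can only add matches. Strand was not used, so an added match can be the span of another gene. Which reason applies to each unmatched gene was not examined. A low share matched therefore does not show that the genes of a list are missing from the table. The counts carry no information on expression.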

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

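No comparison of expression was made, so the alternatives planned before the data were examined were not run. These were other pseudocounts, filters on low FPKM, rescaling of the libraries to equal medians, quantile normalization, conversion to TPM, the removal of small RNA genes, unmatched random lists and lists without shared members. No paired analysis was possible because each group has 1 library.

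The matching of gene lists by position, and its alternatives, were chosen after seeing the data. At a minimum reciprocal overlap of 25%, 75% and 90% in place of 50%, 635, 541 and 492 of the 696 list genes matched a span, against 596. Those with a span of their own numbered 536, 482 and 445, against 517.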
